A study of Homo sapiens with 6 samples.

How the data were processed

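RNA of 6 CAL27 samples was sequenced, 3 wild type and 3 with a targeted TCF19 gene; groups were taken from the genotype given in the labels and replicate numbers from the sample titles. Per the labels' protocols, cells were transfected with Cas9 and a guide plasmid, selected with puromycin and blasticidin and cloned by serial dilution, total RNA was extracted with Trizol, and libraries followed standard Illumina protocols. Per the submitters' processing notes, HISAT2 and GRCh38 were used; versions, the annotation, the counting tool, strand handling and whether multiply aligned reads were counted are not given in the sources used here. Each deposited file listed 54261 gene symbols with 1 value each.

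The unit of the deposited values is stated in neither the labels nor the file headers, and was taken as RPKM from the values: they are not whole, do not sum to a common total, and in genes with 1 exon the product of value and exon length moves in steps of a common size within a library. The steps implied 29400000, 29700000 and 26800000 reads in wild-type replicates 1 to 3 and 31300000, 29300000 and 27800000 in knockout replicates 1 to 3. Within a tolerance of 0.1 step, 49.8% to 52.8% of the low values were whole, so whole reads were not recovered and no count model was run. Whether reads or fragments were counted is not stated. Of the symbols, 28 had been turned into dates, and 17 of these rows were among the genes tested; none is named.

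The design written before the data were examined was for counts, with limma-trend as the test for a normalized unit, and that test was used: values were moved to log2(value + 1), genes with a value of at least 1 in at least 3 samples were kept (12639), and genotype was the only term, leaving 4 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. A fold change is on the log2(value + 1) scale, which understates the change of low genes. Means and SDs are of the deposited values over 3 libraries. The minimum of 5 for named genes, written for CPM, was applied to the deposited values. Single genes at low values were tested by an exact two-sided permutation test, whose smallest p for 3 against 3 is 0.1.

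The 31 gene lists (535 distinct genes) were fixed before the data were examined. The 29 with at least 3 tested genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. The genes named were, by a rule fixed at the same time, TCF19, the 10 highest and 10 lowest protein-coding genes with an adjusted p under 0.05, a mean of at least 5 and no overlap between groups, and up to 4 called members of each list and of each region or family that a test pointed to, by absolute log2 fold change. Members that did not pass are named with their values, and those few, the members that went against the direction of their list and the genes named for the chromosome 6 segment were chosen after their values were seen. A few genes that the rule names are not reported here.

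Gene type and position came from a RefSeq table of GRCh38, which matched 96.6% of the tested genes by symbol. GC content and transcript length came from GENCODE transcripts and were found for 93.8% of them. The guide window was read from the labels in hg19 and matched to the GRCh37 sequence and annotation; coordinates of the builds were not converted or mixed. For position, genes with a mean of at least 5 were ordered along each chromosome and the median log2 fold change, less the genome median, was taken in consecutive windows of 25 genes; windows beyond 0.3 were counted against 1000 shuffles of gene order.

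The fit was tested on simulated data with the 12639 genes and 200 genes changed in each of 5 draws. It recovered 83.8% of changes of 1 and 36.8% of changes of 0.5 on the log2 scale, with 2.7% false calls. The simulated shifted list was called in all 5 draws. Noise was drawn independently for each gene, and far fewer genes were changed than were called in the data (3631). These rates and the list result therefore need not hold for the data. Alternatives were median-ratio, upper-quartile and total scaling, a pseudocount of 0.1, no filter, a mean of at least 5, thresholds on the fold change, the replicate number as a block, each replicate left out, other windows, and, chosen after seeing the data, a correction of each library for its trend on GC content and transcript length and protein-coding genes alone. The gene families were defined and tested after seeing the data, with Benjamini-Hochberg adjustment over 170 families. Tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.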

Results

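The series measured RNA by sequencing in CAL27, an established line of human oral squamous cell carcinoma cells, with 3 wild-type samples and 3 samples in which TCF19 had been targeted with CRISPR/Cas9. TCF19 encodes a nuclear protein with a forkhead-associated domain and a PHD finger. The comparison asked which genes differ in RNA level between knockout and wild-type cells. The deposited values were of the RPKM type (reads scaled by transcript length and library total) and summed to between 412234 and 433340 per library. In genes with 1 exon the low values moved in steps that implied 26800000 to 31300000 reads per library, although only 49.8% to 52.8% of these values lay within 0.1 of a whole number of steps. The labels state that knockout cells were selected as single clones. They do not say whether the 3 knockout samples came from 1 clone or several, nor whether the wild-type cells were cloned. Whether wild-type cells went through the transfection and drug selection was not established here. Differences between clones, effects of transfection or selection and the loss of TCF19 therefore could not be told apart. The same holds for any difference in culture or library preparation between the groups. Nothing states that the samples of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

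TCF19 itself was listed at low values in every library. The 3 wild-type libraries had 0.725, 1.08 and 1.12 and the 3 knockout libraries had 0.758, 0.62 and 0.403, so the groups overlapped. The limma log2 fold change was -0.31 with an SE of 0.137 and an adjusted p of 0.258 in the fit without a filter on low values, and the two-sided exact permutation p was 0.2, where the smallest that 3 against 3 can give is 0.1. The guide window stated in the labels covers bases 31127417 to 31127435 of chromosome 6 in GRCh37 (hg19), which are 19 bases inside the coding part of exon 2 of TCF19 (gene span 31126108 to 31134936, plus strand). On the plus strand these bases read CGCCGAACTGCATGCCGAG, and on the minus strand CTCGGCATGCAGTTCGGCG, which is followed on that strand by TGG, the form of PAM that Cas9 of Streptococcus pyogenes uses. The window holds coding bases 171 to 189. A small insertion or deletion there need not change the RNA level, and no sequence of the edited site was analysed here. Most genes of the chromosome segment around TCF19, including genes that every cell uses such as TUBB, were listed at 0 or close to it in all 6 libraries, so the level of TCF19 did not check the knockout labels.

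**Figure D1:**
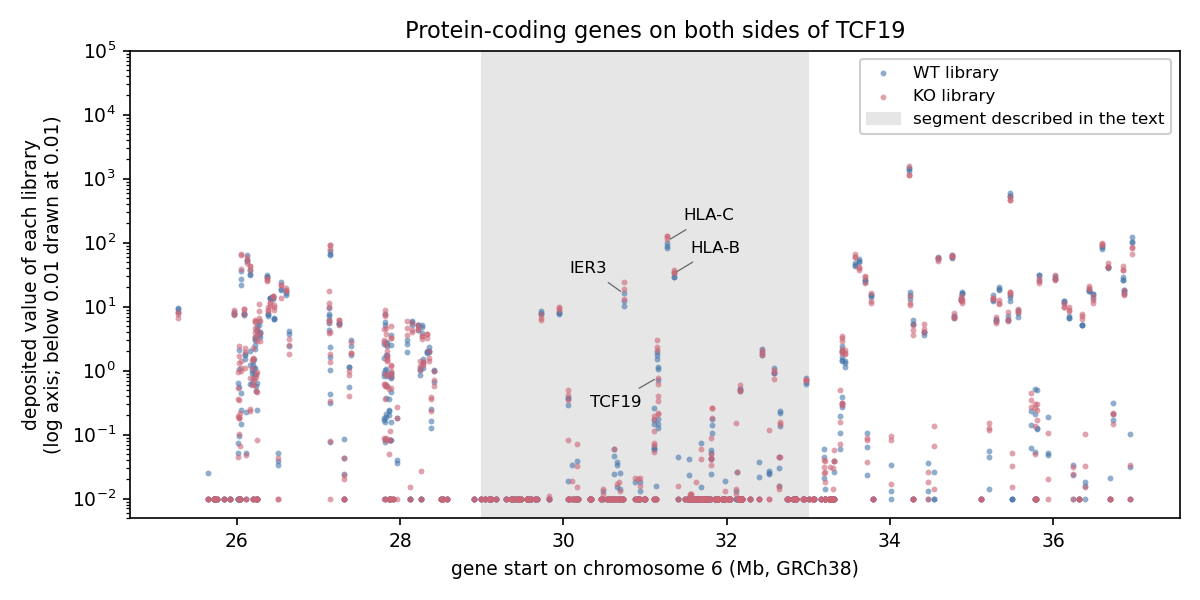
Deposited value of each library (log axis, values below 0.01 drawn at 0.01) against gene start on chromosome 6 (Mb, GRCh38) for protein-coding genes, with wild-type libraries in blue and knockout libraries in red. In the shaded segment from 29 to 33 Mb, which holds TCF19, 7 of 142 genes reach a value of 1 in all 6 libraries.

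Among the genes that fell most in the knockout cells, SERPINB2, which encodes plasminogen activator inhibitor 2, fell from 25.6 ± 1.93 (SD, n = 3) to 0.556 ± 0.133 (SD, n = 3), the lowest log2 fold change of the named genes at -4.09 (SE 0.103, limma adjusted p 4.27e-06). HAS3, a hyaluronan synthase, fell from 19.6 ± 0.304 to 2.79 ± 0.321, the retinol dehydrogenase family gene DHRS9 from 25.7 ± 2.24 to 4.23 ± 0.138, and LCP1, an actin-bundling protein, from 26.8 ± 0.787 to 4.74 ± 0.79. FGFBP1, a carrier of fibroblast growth factors, fell from 60.4 ± 2.59 to 15 ± 3.98, and KRT14, the basal-layer keratin, from 17.3 ± 1.81 to 4.11 ± 1.17. S100A2, a calcium-binding protein of basal epithelium and the most abundant of these genes, fell from 1177 ± 136 to 415 ± 65.2. SERPINB7, the sterol regulator INSIG1 and the interleukin receptor IL6R completed the 10 genes with the lowest fold changes, with log2 fold changes of -1.75, -1.57 and -1.46.

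The genes that rose most included several secreted immune mediators. IL17C, an epithelial cytokine, rose from 1.35 ± 0.599 to 12.7 ± 1.59 (SD, n = 3 in each group), a log2 fold change of 2.56 (SE 0.18, limma adjusted p 0.000208). IL6 rose from 1.74 ± 0.138 to 11.7 ± 1.83 and CXCL10, an interferon-induced chemokine, from 2.11 ± 0.326 to 13.5 ± 3.49. The acute-phase protease inhibitor SERPINA3 rose from 58.6 ± 5.59 to 304 ± 23.7, and SERPINA1 from 4.55 ± 0.975 to 18.3 ± 1.14. KRT6B, a keratin of activated keratinocytes whose reads can be shared with its near-identical paralogs, rose from 4.71 ± 0.588 to 31.0 ± 6.79. The Wnt ligand WNT10A rose from 1.09 ± 0.0719 to 9.02 ± 0.972, and KREMEN2, a receptor of Wnt inhibitors, from 13.9 ± 1.18 to 54.8 ± 5.93. The aldose reductase AKR1B1 rose from 70.7 ± 4.19 to 317 ± 43.8 and thymidine phosphorylase, TYMP, from 13.39 ± 0.281 to 51.9 ± 2.12. In the test against a 1.5-fold change 19 of these 20 genes passed and INSIG1 did not (limma adjusted p 0.162). Under each of the other alternatives in which they were tested the 20 genes kept their call and direction.

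**Figure D2:**
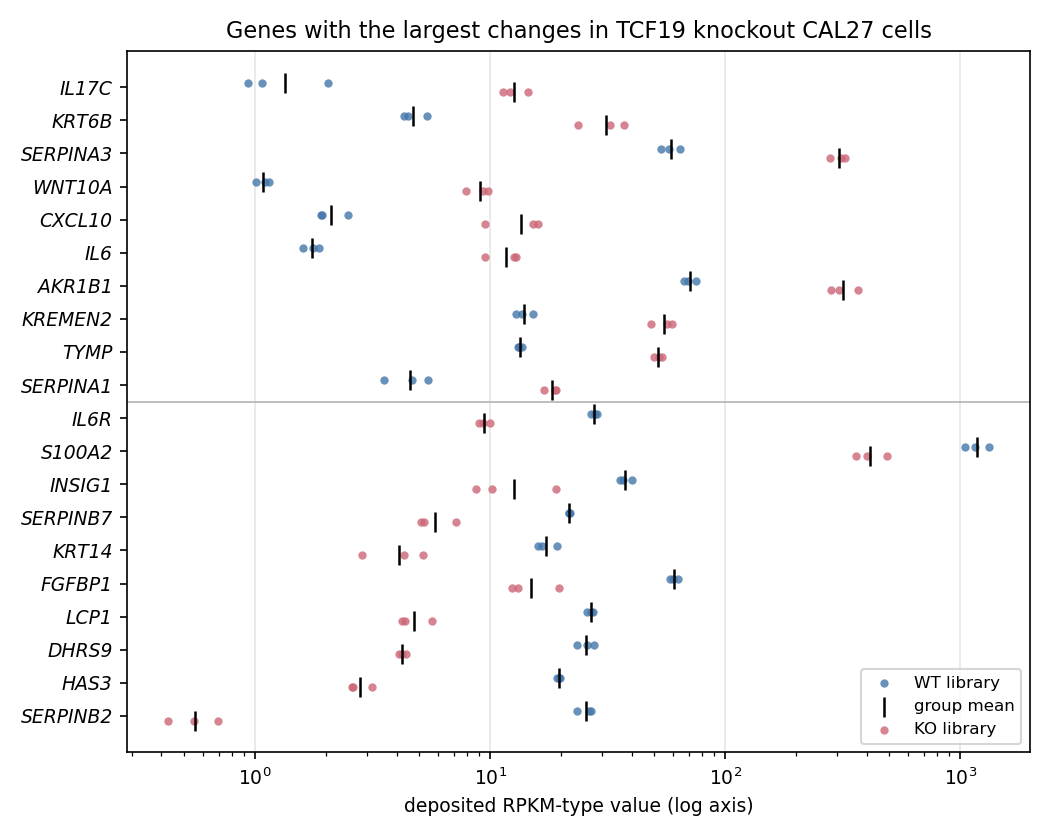
Deposited RPKM-type value (log axis) of each library for the 10 genes with the highest and the 10 with the lowest log2 fold change, with wild-type libraries in blue, knockout libraries in red and black bars at group means (n = 3). SERPINB2 lies between 23.4 and 27 in wild type and between 0.428 and 0.694 in knockout, and no gene has overlapping groups.

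Across the 12639 genes tested, limma called 3631 (28.7%) at an adjusted p under 0.05, 1819 higher and 1812 lower in knockout cells, of which 3312 were protein-coding. Most changes were small: the median absolute log2 fold change of the called genes was 0.47, and 195 genes (106 higher and 89 lower) changed by at least 1 on the log2 scale. The values of the 2 groups did not overlap in 5613 genes (44.4%, against 10% by chance). The count was 2233 without WT replicate 2 and 1890 without WT replicate 3, and 97 genes (64 higher, 33 lower) passed a test against a 1.5-fold change. Upper-quartile scaling raised the share of higher genes among the calls from 50.1% to 63.6%.

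Genes of DNA synthesis rose together. In the list of G1/S and DNA replication genes 20 of 24 tested members rose and 0 fell (20 and 0 adjusted over the list alone), with a median log2 fold change of 0.51. RRM2, a subunit of ribonucleotide reductase, rose from 54.7 ± 4.09 to 101.7 ± 10.1 (SD, n = 3), the transcription factor E2F1 from 12.8 ± 1.2 to 22.9 ± 2.0 and the licensing factor CDT1 from 25.3 ± 2.4 to 42.4 ± 2.83. The list's camera adjusted p was 9e-10 with a preset correlation, and the adjusted p = 0.15 with an estimated correlation. In the list of G2/M and mitosis genes 11 of 22 rose and 1 fell (11 and 3 adjusted over the list alone; camera adjusted p 0.00438, and adjusted p = 0.512 with an estimated correlation). KIF20A, UBE2C and BIRC5, genes of late mitosis and of the chromosomal passenger complex, rose with log2 fold changes of 0.7, 0.61 and 0.58. The 1 member that fell was the proliferation marker MKI67, from 27.0 ± 4.56 to 17.8 ± 2.1, and its adjusted p was 0.0195. That call was lost without a filter on low values (adjusted p 0.0768) and without WT replicate 2 (0.0687), WT replicate 3 (0.0754), KO replicate 1 (0.0502) or KO replicate 2 (0.0633).

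Inflammatory and interferon-induced genes were mostly higher in knockout cells. Of 17 tested NF-kB targets and cytokines 12 rose and 2 fell (12 and 2 adjusted over the list alone), with a median of 0.57, a camera adjusted p of 5.07e-06 and an adjusted p = 0.359 with an estimated correlation. Besides IL6, the chemokine CCL2 rose from 4.73 ± 0.387 to 16.2 ± 1.89, CXCL3 from 7.16 ± 0.847 to 22 ± 1.98 and the growth factor CSF2 from 6.8 ± 0.09 to 18 ± 3.2 (SD, n = 3). The members that fell were the cytokine IL1B, from 309 ± 12.7 to 183.6 ± 18, and PTGS2, whose call was lost under 10 of 14 alternatives, including all that left out a replicate except WT replicate 1 (adjusted p 0.0557 to 0.164). Of 23 interferon-stimulated genes 13 rose and 0 fell (14 and 0 adjusted over the list alone; camera adjusted p 4.84e-05, and adjusted p = 0.437 with an estimated correlation). ISG15, a ubiquitin-like modifier, rose from 220.1 ± 6.6 to 528 ± 59.2, OASL from 10.6 ± 0.48 to 33 ± 5.73, IFIT1 from 6.57 ± 1.14 to 16.9 ± 2.68 and MX2 from 4.21 ± 0.309 to 8.91 ± 1.51. Among 9 tested genes of MHC class I antigen presentation 2 rose and 0 fell (2 and 0 adjusted over the list alone), and the list did not pass (camera adjusted p 0.0579). They were the immunoproteasome subunit PSMB10, with a log2 fold change of 0.53, and HLA-C, with 0.43, whose call was lost after correction for GC content and length (adjusted p 0.0932).

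Genes of the basal keratinocyte were mostly lower. Of 15 tested members 9 fell and 3 rose (10 and 3 adjusted over the list alone), the median was -0.58, the camera adjusted p was 0.00258 and the adjusted p = 0.224 with an estimated correlation. Besides KRT14, the keratin KRT15 fell from 27.0 ± 1.65 to 10.4 ± 0.754, the laminin receptor subunit ITGA6 from 137.5 ± 11.8 to 56.0 ± 4.75 and TP63, the transcription factor of the basal layer, from 67.7 ± 0.638 to 29.3 ± 1.8 (SD, n = 3). The members that rose were the collagen COL7A1, from 5.27 ± 0.0981 to 11.1 ± 0.844, KRT17, from 201.4 ± 21.4 to 384 ± 45.8, and the laminin chain LAMB3, from 187.7 ± 17.6 to 270.2 ± 19.4. KRT5, the usual partner of KRT14, was at 232.5 ± 16.6 in wild-type and 224.5 ± 20.3 in knockout cells and did not pass (adjusted p 0.683). The list of EGFR ligands and MAPK output, which holds the receptor, its ligands and genes induced by the pathway, had 10 of 19 members lower and 2 higher (11 and 2 adjusted over the list alone; camera adjusted p 0.00164, and adjusted p = 0.429 with an estimated correlation). The phosphatase DUSP5 fell from 48.3 ± 4.3 to 22.7 ± 2.54, the ligand AREG from 61.6 ± 5.67 to 33.9 ± 7.29, DUSP6 from 13.9 ± 0.443 to 7.96 ± 1.71 and EGFR itself from 249 ± 6.8 to 159.1 ± 5.66. The transcription factor ETV5 rose from 12.1 ± 1.45 to 18.3 ± 1.81, and so did EGR1, whose call was lost under 7 of 15 alternatives, including all that left out a replicate except KO replicate 3 (adjusted p 0.0614 to 0.113). Cholesterol synthesis genes fell in 8 of 18 cases and rose in 0 (10 and 0 adjusted over the list alone; camera adjusted p 0.000401, and adjusted p = 0.429 with an estimated correlation). Besides INSIG1, the synthase HMGCS1 fell from 41.5 ± 2.07 to 19.6 ± 3.26 (SD, n = 3).

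**Figure D3:**
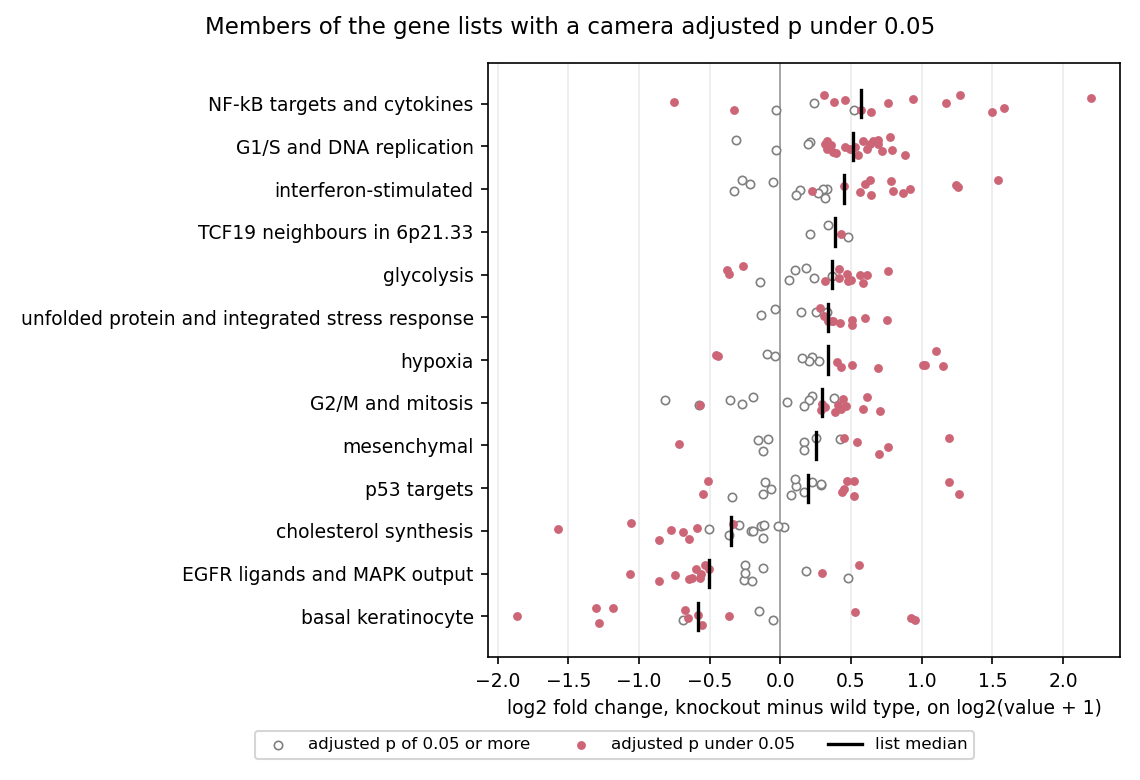
Log2 fold change (knockout minus wild type, on log2(value + 1)) of every tested member of the 13 gene lists with a camera adjusted p under 0.05, with red points for members at an adjusted p under 0.05, open points for the others and a black bar at each list's median. The medians run from -0.58 for basal keratinocyte genes to 0.57 for NF-kB targets and cytokines.

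Genes of oxygen sensing, glycolysis and protein stress mostly rose where they changed. Of 16 hypoxia genes 8 rose and 2 fell (10 and 2 adjusted over the list alone; camera adjusted p 0.000963, and adjusted p = 0.362 with an estimated correlation). The carbonic anhydrase CA9 rose from 52.8 ± 2.01 to 118.6 ± 2.02, ANKRD37 from 5.98 ± 0.329 to 14.0 ± 1.82, ANGPTL4 from 14.4 ± 1.87 to 30.5 ± 4.45 and the prolyl hydroxylase subunit P4HA2 from 18 ± 0.231 to 37.3 ± 3.3 (SD, n = 3). EGLN3 and MXI1 fell, with log2 fold changes of -0.45 and -0.44. The EGLN3 call was lost under 2 of 15 alternatives (without WT replicate 2, adjusted p 0.0503) and the MXI1 call under 8 (0.0591 to 0.142), among others without WT replicate 2, WT replicate 3, KO replicate 2 or KO replicate 3. Of 19 glycolysis genes 10 rose and 3 fell (12 and 3 adjusted over the list alone; camera adjusted p 0.00138, and adjusted p = 0.437 with an estimated correlation), with PGAM1 at a log2 fold change of 0.76 and TPI1 at 0.61. PFKM, PFKP and HK2 fell, with log2 fold changes of -0.38, -0.36 and -0.26, and all 3 calls were lost under upper-quartile scaling (adjusted p 0.0985, 0.106 and 0.14). The HK2 call was lost under 8 of 15 alternatives, including all that left out a replicate except KO replicate 3 (adjusted p 0.053 to 0.14). Of 15 genes of the unfolded protein and integrated stress response 10 rose and 0 fell (11 and 0 adjusted over the list alone; camera adjusted p 4.84e-05, and adjusted p = 0.15 with an estimated correlation). The transcription factors XBP1 and DDIT3 rose from 32.3 ± 3.68 to 55.0 ± 3.42 and from 11.3 ± 0.327 to 17.6 ± 0.434.

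Of 20 p53 targets 7 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p 0.0236, lost after correction for GC content and length at 0.0599, and adjusted p = 0.359 with an estimated correlation). BBC3, which encodes the proapoptotic protein PUMA, rose from 8.42 ± 0.216 to 21.7 ± 2.07 and GDF15, a stress-induced cytokine, from 21.2 ± 1.91 to 49.8 ± 6.04 (SD, n = 3), whereas CDKN1A, the p53-induced cell cycle inhibitor, was at 41.4 ± 0.834 and 43.7 ± 3.42 and did not pass (adjusted p 0.465). The members that fell were MDM2, the main inhibitor of p53, from 8.98 ± 1.68 to 5.83 ± 1.25, and ZMAT3, from 3.38 ± 0.479 to 2.08 ± 0.352. The MDM2 call was lost under 6 of 15 alternatives (adjusted p 0.0639 to 0.144) and the ZMAT3 call under 5 of 14 (0.0612 to 0.0885), both among others without WT replicate 2, WT replicate 3, KO replicate 1 or KO replicate 2. Of 13 mesenchymal genes 5 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p 0.0236, and adjusted p = 0.359 with an estimated correlation). The rest of the 21 listed genes were below the filter and not tested. Among them were VIM (0.894 to 0.996 in wild-type and 0.807 to 0.905 in knockout libraries) and TAGLN (0.389 to 0.699 and 0.614 to 0.944). The collagen COL5A1 rose from 16.8 ± 1.57 to 39.8 ± 5.04, SNAI1 from 4.02 ± 0.312 to 7.52 ± 0.958 and SPARC from 154.2 ± 11.8 to 250.3 ± 9.95, while SNAI2, a relative of SNAI1, fell from 8.36 ± 0.458 to 4.7 ± 0.211. The list of genes near TCF19 also passed (camera adjusted p 0.0466, and adjusted p = 0.359 with an estimated correlation), but rested on 4 tested genes, of which 1, HLA-C, rose and 0 fell (3 and 0 adjusted over the list alone), and lost its call under 8 of 12 alternatives. Over the 13 lists that passed, 99 of 140 called members kept their call under each alternative in which they were tested other than the stricter fold thresholds. Of these 140 members 36 lost it when 1 of the replicates was left out, and 0 reversed.

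The other lists did not pass camera at the preset correlation, although single members changed. For each of them the values in parentheses are the numbers higher and lower adjusted over the list alone, the numbers that kept their call under each alternative in which they were tested other than the stricter fold thresholds, and the camera adjusted p. In the list of matrix proteases and their inhibitors 4 of 12 rose and 2 fell (4 and 3; 1 and 1; 0.585). In that of epithelial junctions 4 of 18 rose and 8 fell (4 and 8; 3 and 2; 0.546), with the splicing regulator ESRP1 lower, from 27.6 ± 1.6 to 17.4 ± 1.62, and the plakophilin PKP3 higher, from 55.7 ± 2.12 to 87.0 ± 1.98 (SD, n = 3). Squamous differentiation had 0 of 10 higher and 3 lower (0 and 3; 0 and 2; 0.274). The cornified envelope gene SPRR1B was one of these and was listed at 0 in all 3 knockout libraries. NRF2 targets had 1 of 14 higher and 4 lower (1 and 8; 1 and 1; 0.109), with SRXN1 lower. TGF-beta and YAP targets had 5 of 14 higher and 4 lower (5 and 4; 4 and 3; 0.392). WNT targets and ligands had 4 of 9 higher and 4 lower (4 and 5; 3 and 2; 0.964), and Notch pathway genes 4 of 10 higher and 2 lower (4 and 2; 2 and 2; 0.392). The rest of the 16 listed WNT genes were below the filter and not tested. In wild-type and knockout libraries AXIN2 was at 0.0168 to 0.0766 and 0.261 to 0.47. SP5 was at 0.422 to 0.6 and 0.74 to 1.1, and NOTUM at 0.0168 to 0.121 and 0.211 to 0.385. NKD1 was at 0.148 to 0.206 and 0.273 to 0.28, and SFRP1 at 0.259 to 0.354 and 0.491 to 1.04. WNT5A was at 0.395 to 0.508 and 0.303 to 0.396, and LGR5 at 0 in all libraries but WT replicate 2 (0.0073). NOTCH3 rose from 25.2 ± 3.52 to 56.8 ± 3.97, and the activin subunit INHBA from 13.7 ± 2.12 to 37.3 ± 11.7. Apoptosis regulators had 5 of 15 higher and 1 lower (5 and 1; 3 and 0; 0.274). DNA repair genes had 3 of 20 higher and 0 lower (3 and 0; 3 and 0; 0.274). Fatty acid synthesis genes had 2 of 12 higher and 2 lower (2 and 4; 1 and 1; 0.501), and MYC and ribosome biogenesis genes 0 of 19 higher and 3 lower (0 and 3; 0 and 1; 0.274), with MYC itself down from 68.8 ± 2.7 to 44.4 ± 6.92. Nuclear-encoded oxidative phosphorylation genes had 3 of 20 higher and 1 lower (2 and 1; 2 and 0; 0.392). Mitochondrially encoded genes had 0 of 13 higher and 1 lower (0 and 1; 0 and 0; 0.19). The NDUFA4 call (lower) was lost under 10 of 14 alternatives, including all that left out a replicate except KO replicate 2 (adjusted p 0.0517 to 0.26). The SDHB call (higher) was lost under 6 of 15, including all but KO replicate 3 (0.0575 to 0.152). The mitochondrial ND5 call (lower) was lost under 5 of 15 (0.0509 to 0.124), among others without WT replicate 2, WT replicate 3 or KO replicate 1. Of 5 stemness markers 1 rose and 2 fell (1 and 3; 1 and 2; 0.21), with CD44 down from 418 ± 3.26 to 276.3 ± 6.1.

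Markers of other cell types were few. Of 4 tested leukocyte markers 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p 0.19), led by CD74, which rose from 158.7 ± 13.2 to 244.6 ± 9.94 (SD, n = 3) and which epithelial cells can also express. The call of CD14, the other that rose, was lost after correction for GC content and length (adjusted p 0.0587). The call of CSF1R, which fell, was lost under 8 of 14 alternatives, including each that left out a replicate (adjusted p 0.0531 to 0.151). Among fibroblast markers 2 were tested, of which LUM fell from 3.01 ± 0.506 to 0.691 ± 0.156 and PDGFRB rose from 2.54 ± 0.086 to 4.83 ± 0.648. Among endothelial markers 1 was tested, CDH5, at 2.47 ± 0.213 in wild-type and 3.1 ± 0.655 in knockout cells, and it did not pass (adjusted p 0.243). These last 2 lists held too few tested genes for a list test. No list had an adjusted p under 0.05 with an estimated correlation, the smallest being 0.15 (3 lists had an unadjusted p under 0.05), and fry, which tests whether a list's genes move one way on balance without comparing them with other genes, called 19 of 29. Of the lists that passed camera, fry did not call G2/M and mitosis (fry adjusted p 0.0562). It did call NRF2 targets (fry adjusted p 0.00392), stemness markers (0.00392), leukocyte markers (0.01) and WNT targets and ligands (0.0122). It also called matrix proteases (0.017), MHC class I antigen presentation (0.0243) and squamous differentiation (0.04).

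Fold changes moved with the composition of the transcript. Across 11850 genes, which are not independent replicates, Spearman's rho between log2 fold change and GC content was 0.318, and with transcript length it was -0.196. The median log2 fold change rose from -0.156 in quartile 1 of GC content (lowest) to 0.116 in quartile 4 (highest). Along the chromosomes, 2 of 307 consecutive windows of 25 genes had a median more than 0.3 from the genome median. Over 1000 shuffles of gene order there were 0.04 such windows on average and at most 2 (shuffle p 0.002). The shuffles ignored GC content, with which fold changes moved, so the shuffle p does not separate position from composition. After correction for GC content and length there were 0 such windows. Leaving out 1 replicate gave from 1 (without KO replicate 1, KO replicate 2 or WT replicate 3) to 10 (without KO replicate 3).

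**Figure D4:**
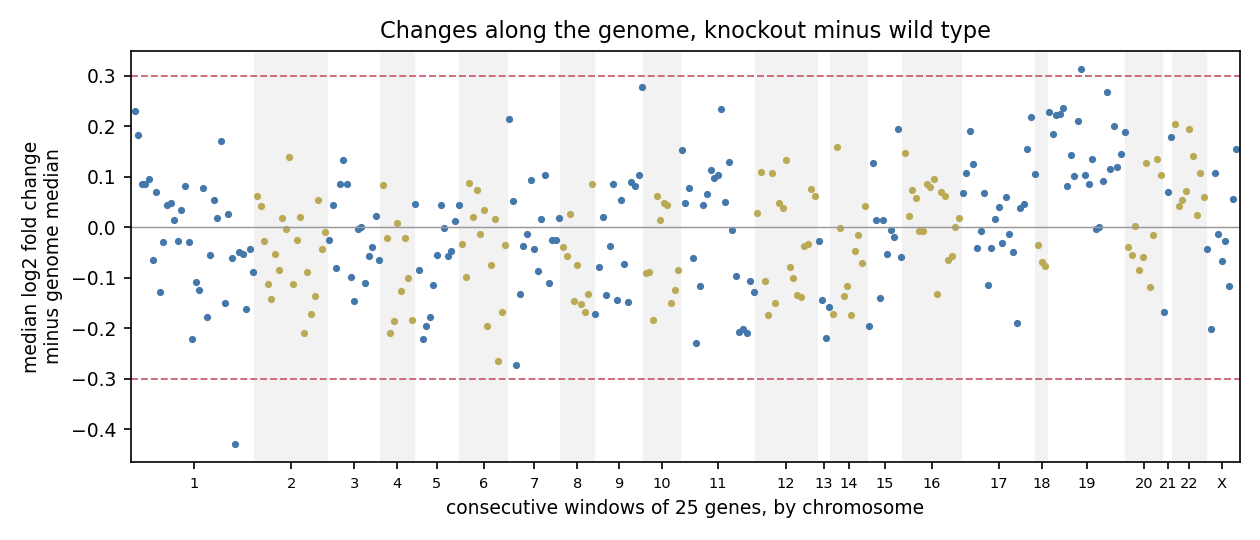
Median log2 fold change (knockout minus wild type, less the genome median) in 307 consecutive windows of 25 genes ordered by chromosome, with dashed lines at 0.3 and -0.3. Of these windows 2 lie outside the lines, at -0.43 on chromosome 1 and at 0.31 on chromosome 19.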

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

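The correction for GC content and length and the use of protein-coding genes alone were chosen after seeing the data. Against 3631 called genes, the other scalings, pseudocount 0.1, no filter, a mean of at least 5, the GC and length correction and protein-coding genes gave 2585 to 4318. Of the original calls, 82.9% kept their call and sign under upper-quartile scaling and 61.6% with no filter, where more genes are tested. A log2 fold change of at least 1 left 195 genes and a test against 1.5-fold left 97, both stricter by construction. Leaving out 1 replicate gave 1890 (WT replicate 3) to 3717, with 2233 without WT replicate 2. Of 31 lists, 13 were called, and 0 with an estimated correlation (fry 19); leaving out 1 replicate gave 12 to 14. The TCF19 log2 fold change stayed below 0, from -0.22 to -0.65, and past no threshold. Over 132 genes with 1965 values under alternatives other than the stricter fold thresholds, 1844 kept call and direction, 121 kept direction without the call, and 0 reversed. Against 2 genome windows beyond 0.3 (0.04 on average in shuffles), windows of 10 genes gave 29 (8.99 on average and at most 17 in shuffles). Windows of 50 genes gave 0, a limit of 0.5 gave 0 and a mean of at least 1 gave 5. The GC and length correction gave 0, and leaving out 1 replicate 1 to 10. Why the count moved between settings was not tested. Explanations of the run on chromosome 1 are weighed under the other observations. With replicate numbers as a block 3987 genes were called. The numbers did not pair the samples: deviations from the group means correlated at 0.327, -0.303 and 0.41 for pairs 1, 2 and 3, and not every sample correlated best with its own number. The planned count models (edgeR with its filter, DESeq2, limma-voom) were not run, since the values are not counts. What depth limits was not tested.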

Other observations

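The tests of the chromosome 6 segment, the run of genes on 1q25, the gene families and the GC and length correction were chosen only after the results were seen. Among 170 gene families defined by symbol stem with at least 8 tested protein-coding members, 3 passed camera. Genes of the large subunit of the mitochondrial ribosome (MRPL) were higher, with 19 of 48 called higher and 0 lower (adjusted p 0.022), a median log2 fold change of 0.165 and an adjusted p = 0.969 with an estimated correlation. MRPL33 rose from 28.2 ± 3.01 to 49.9 ± 8.27 and MRPL28 from 101.2 ± 4.87 to 139.8 ± 8.81 (SD, n = 3). Under total scaling 17 were higher and 2 lower, and after the GC and length correction 14 were higher and 3 lower and the family no longer passed (median 0.12, adjusted p 0.189). The genes with the symbol stem MCM, some of them in the replication list, had 7 of 10 higher and 0 lower (camera adjusted p 0.022, and adjusted p = 0.969 with an estimated correlation). Their call was lost under upper-quartile scaling at 0.0547. There the median log2 fold change was 0.504 against 0.429, and 7 were still higher and 0 lower. The GALNT genes, which start O-linked glycosylation, had 6 of 8 lower and 0 higher (adjusted p 0.0443, lost under upper-quartile scaling at 0.0516, where the median was -0.259 and 3 were lower, and adjusted p = 0.969 with an estimated correlation), a median of -0.333, and 3 to 6 lower under the other scalings. GALNT7 fell from 11.1 ± 1.54 to 5.51 ± 0.935 and GALNT3 from 16.6 ± 2.55 to 8.73 ± 1.33.

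The first pattern weighed is the 3631 called genes. Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 3631 and the highest of the others gave 0; 1 of 10 is the smallest share possible, so the splits are too few for a share under 0.05. With limma at an unadjusted p under 0.05 the real split gave 5248 and the others 74 to 1994. A trend on GC content and length as the whole cause is argued against by the 83.2% of calls kept with the same sign after its removal, and library scaling by the 82.9% or more kept under each of 3 other scalings. The loss of TCF19, differences between clones, effects of transfection or drug selection and differences in culture or library preparation between the groups stay open. The labels do not say how many clones the samples came from, and the handling of wild-type cells was not established here.

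The second pattern is the segment of chromosome 6 from 29 to 33 Mb (GRCh38, bounds chosen from the values), where 90 of 142 protein-coding genes are listed at 0 in all 6 libraries and 7 reach 1 in all, against 457 of 858 elsewhere on the chromosome. TUBB, BAG6, FLOT1 and DDX39B are listed at 0 in every library. The bounds do not hold the whole run. TRIM27, which starts at 28903002, and WDR46 and PFDN6, at 33279108 and 33289197, are also listed at 0 in all 6 libraries. Such genes are counted as elsewhere on the chromosome. Loss of the whole segment from the cells is argued against by those 7 genes, such as HLA-B and HLA-C. Reads shared with alternative haplotype copies of the segment in the aligned genome are a candidate explanation: RPS9, in the other large region with such copies, 19q13.42, is at most 0.116, and RPS9 and RPS18, which lies just past the segment's end, are the only ribosomal protein genes of 78 below 1 in all libraries. Whether the authors' index held such copies is not stated.

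The third pattern is the run of lower genes on chromosome 1 from 173824673 to 181061938 (GRCh38), the window with a median of -0.43, 1 of 2 of 307 beyond 0.3 (shuffle p 0.002); there were 0 such windows after the GC and length correction, 1 without KO replicate 1, KO replicate 2 or WT replicate 3, 10 without KO replicate 3 and 8 without WT replicate 1. A regional copy number difference of the knockout clone, which the design allows, would lower protein-coding genes there as well. The lower of 2 protein-coding windows over the region has a median of -0.14, short of the -0.3 limit. Those windows also hold genes outside the region, and leaving out noncoding rows that are all lower cannot lower a median. Protein-coding genes of the run went both ways, from -0.88 for RASAL2 and -0.82 for RFWD2 to 0.53 for TOR1AIP1. The windows therefore cannot exclude a difference over part of the region. With protein-coding genes alone, the windows beyond 0.3 were 2 others, on chromosomes 6 and 11. Several rows of 1 host gene could also give such a run: GAS5 and 6 small nucleolar RNAs inside it are 7 of the 25 rows (28%), and 7 of the 13 rows below -0.3 (53.8%), with a median of -0.777 against -0.13 for the rows outside GAS5, although leaving out only low rows must raise a median. The test written for this explanation needed most of all 25 rows to lie inside GAS5, a share that no fold change could alter. It would have rejected the explanation had most of the low rows lain outside. Neither held, and the test could not have come out in favour, so this explanation stays open.

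The 4 tested genes within 1 Mb of TCF19 had a median log2 fold change of 0.384 against -0.031 for the other 12635 genes (p 0.027 against 10000 random sets of 4 genes, which are not independent replicates). They are the 4 tested genes of the list of TCF19 neighbours, whose adjusted p = 0.359 with an estimated correlation and whose call was lost under 8 of 12 alternatives. The other 86 protein-coding genes there were below the filter, in a segment where TUBB and BAG6 are also listed at 0, so these 4 do not describe the region. The second principal component (20.1% of the variance, against 59.9% for the first, which separates the genotypes) set WT replicate 1 and KO replicates 1 and 2, at 17.4, 9.3 and 5.5, apart from WT replicates 2 and 3 and KO replicate 3, at -5.4, -7.0 and -19.8. The labels give no batch.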
